A study of Bombyx mori with 6 samples.

How the data were processed

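The series holds 6 RNA sequencing libraries of testis from silkworm larvae on day 5 of the fifth instar, 3 from the wild-type strain 898WB (WT) and 3 from the genetic male sterile line (GMS). Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit, whose reads do not mark the strand, so reads of a gene and an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, HISAT2 2.1.0 and featureCounts 1.6.2 were used. The genome build and annotation are not given in the sources used here.

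The deposited table gives raw read counts per gene for all 6 libraries, as whole numbers, per the file headers. The authors also deposited RPKM values per gene for each library. Gene lengths recovered from counts and RPKM were whole within 0.01 for 100% of genes with reads, and the RPKM values were scaled to 48248888 to 68701498 reads per library, of which 40.1% to 42.5% were in the count table. Of 15884 genes, 825 had no reads in any library. The counts carry NCBI gene numbers. The RefSeq gene table of assembly ASM3026992v2 gave a symbol for 13030 of them, and the other 2854, written GeneID and a number, took 4.36% to 4.67% of the counts. Only 1839 had a symbol other than a LOC number, 407 of these microRNAs. No coordinate of that assembly is printed, since the authors' build is unknown. It was used for names and for which genes are neighbours.

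Library totals ran from 19627477 to 28358501 counts, so a floor of 3 counts was 0.106 to 0.153 CPM in a single library. Floors and counting intervals (95%, exact binomial) cover counting error only. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, the filterByExpr filter (12029 genes kept and 3855 removed), group as the only term and Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were tested.

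Of 36 lists fixed before the data were examined, 7 reached 5 tested members, because they were written as product names and the gene table holds symbols only. A further 23 lists of symbols were written after the identifiers had been seen and before any test, and 21 of these reached 5 members. They were adjusted as a separate family. The symbol lists not described in the report were not called by camera over all 6 libraries, with rises and falls of 7 and 0 of 28 cell cycle genes, 4 and 0 of 12 DNA damage genes, 4 and 0 of 10 sex determination genes, 0 and 5 of 16 translation factors, 1 and 4 of 22 mitochondrial genes, 0 and 2 of 7 redox genes, 2 and 4 of 18 secretory pathway genes, 10 and 7 of 42 chemosensory genes and 3 and 4 of 22 signalling genes. Without WT replicate 3 camera called the DNA damage list higher (adjusted p = 0.0417) and the translation factor list lower (adjusted p = 0.0345), both at an adjusted p of 0.495 with an estimated correlation. Over all 6 libraries fry, which does not compare a list with other genes, called 7 of these lists, all but those of translation factors and signalling.

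Genes were named by a rule set before the data were examined. Among genes with adjusted p under 0.05, a change of at least 2-fold, a mean of at least 5 CPM and no overlap between the groups, it takes the 12 largest rises and the 12 largest falls with a real name, and the 3 largest rises and the 3 largest falls of any name. It adds up to 4 members of smallest p of each list, or the 2 most abundant where none passed, the 3 most abundant genes of each group and up to 3 genes per direction seen in 1 strain only. Some genes the rule takes from lists are not described one by one, and 1 gene it takes is not reported here. Osi18, Osi7, CPR25, CPT1, CPH20, CPH22, Enb3, CecB1, Sp1 and Sp2 lie outside the rule and were chosen after their values were seen, as were genes named for WT replicate 3 in the closing section.

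On simulated counts with 200 changed genes, of 11880 tested, the edgeR test recovered 55.2% of 67 genes at 1.5-fold, 85.1% of 67 at 2-fold and 98.5% of 66 at 4-fold, with 9 false calls. In 10 simulated sets with no change, at most 3 genes were called in a set and 1 list in all of them together. Genes were drawn independently, so list members were not correlated and no library stood apart. The list count therefore does not carry over to the real data. Only 200 genes were changed in the simulation, against 4357 called in the data, and the adjusted threshold is stricter where fewer genes change. The recovered shares therefore do not carry over either. The neighbour test called 10 of 200 random sets of 10527 genes. It called 5 of 20 sets with 5 planted blocks of 5 genes, 19 of 20 with 10 blocks and 20 of 20 with 20 blocks. The planted blocks were set anew once, after a first version with fewer and longer blocks narrowly missed the threshold.

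Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors and filters, RPKM values tested with limma on the log2 scale with a pseudocount of 1 or 0.1, the replicate number as a block, leaving out each library, an estimated correlation, also without each library, fry, and other minimums. All pairs of replicates within a group differed by more than sampling noise, with chi-square per degree of freedom from 2.67 to 38.2.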

Results

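Transcript levels were measured by RNA sequencing in testes of the silkworm Bombyx mori, taken on day 5 of the fifth larval instar. Testes of a genetic male sterile line, here called GMS, were compared with testes of the wild-type strain 898WB, here called WT, with 3 libraries in each group. The deposited table held read counts for 15884 genes. The WT libraries held 28358501, 25492937 and 21690617 counted reads and the GMS libraries 19627477, 23529412 and 27941504. The labels call the libraries biological replicates and do not say whether each came from 1 animal or from a pool, so p-values measure the spread between these libraries only.

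The libraries separated first by strain. The first principal component of log2 CPM, the normalised read count scaled to library size, held 81.6% of the variance, with the WT libraries between -52.5 and -39.8 and the GMS libraries between 46.7 and 48.1. WT replicate 3 stood apart on the second component, which held 11%. Its correlation with WT replicates 1 and 2 across genes was 0.985 and 0.982, against 0.995 between those 2 libraries and 0.995, 0.995 and 0.995 between the GMS libraries. A total of 195 genes with a mean of at least 5 CPM were over 2-fold higher in WT replicate 3 than in both other WT libraries, and 15 were over 2-fold lower. The same comparison gave 2 higher and 2 lower genes for WT replicate 1, and 0 higher and 6 lower for WT replicate 2. The most abundant transcripts were shared by both strains: the beta-tubulin Tub4 stood at 32823 ± 2535 CPM in WT and 24830 ± 359 CPM in GMS (SD, n = 3), followed by LOC100101153 and the alpha-tubulin Tua3.

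**Figure D1:**
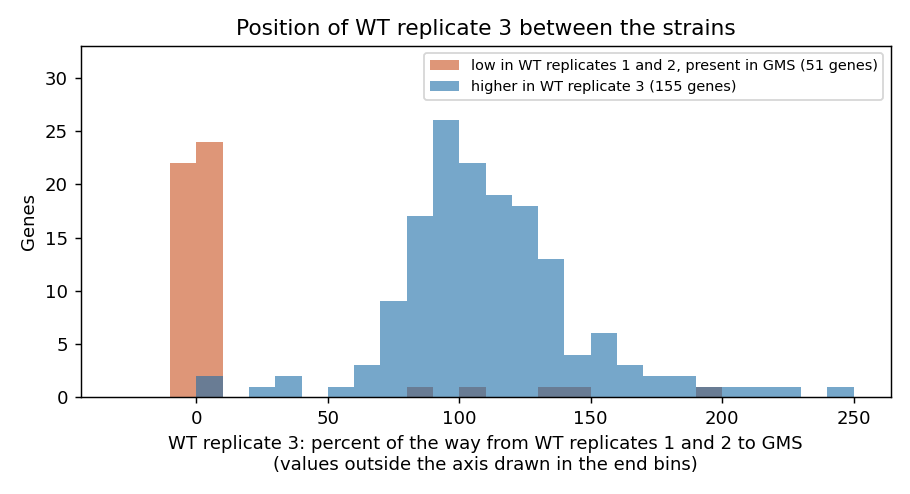
Position of WT replicate 3 on the way from WT replicates 1 and 2 (0%) to the GMS mean (100%), as a count of genes. Blue bars are 155 genes over 2-fold higher in WT replicate 3 and also over 2-fold higher in GMS, with a median of 108%, and orange bars are 51 genes under 1 CPM in WT replicates 1 and 2 and at 5 CPM or more in GMS, with a median of 0.01%; 7 genes are in both.

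The comparison of GMS with WT asks which testis transcripts differ between the sterile line and the fertile strain. Among genes with a name, the cuticular protein genes CPH21 and CPH18, the Osiris genes Osi19 and Osi9 and the antimicrobial peptide genes Attacin1 and Leb3 were higher in GMS. The haemolymph lipoprotein genes LP3 and LP4 and the detoxification genes UGT41A2 and GSTe5 were lower. Of 12 germ cell and meiosis genes 3 rose, 2 fell and 7 did not pass, and of 7 tubulin genes 0 rose and 5 fell. Tub4, which fell, is in both lists. Of 12029 genes tested, 4357 differed, 2115 higher and 2242 lower in GMS, and 1238 of them differed by at least 2-fold, 606 higher and 632 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Without WT replicate 3 the counts were 7104 and 1585, and the balance at 2-fold turned, to 864 higher and 721 lower. A total of 1177 of the genes with at least a 2-fold difference were called both ways. The balance of directions also depended on scaling and test: with library totals only, 3264 genes were higher and 1695 lower, 696 and 556 at 2-fold, and the median of all genes moved from 0.05 to 0.15 on the log2 scale. With RPKM values the split was 2597 and 1765, and with limma-voom it was 2396 and 2282, 687 and 638 at 2-fold. The groups did not overlap for 6132 genes, 51.0% of those tested, where chance gives 10%.

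Cuticular protein genes gave large rises. CPH21 (gene 100379475) stood at 0.0934 ± 0.0405 CPM in WT and 83.4 ± 1.98 CPM in GMS (SD, n = 3), with 7 reads over the 3 WT libraries against 6137 in GMS. The ratio of these counts was 868, with a 95% counting interval of 421 to 2160. CPH18 rose from 0.137 ± 0.0127 to 69.2 ± 6.82 CPM. CPH23, CPH19, CPT3, CPG20 and CPR70 rose by 6.87, 5.18, 7.58, 6.19 and 4.86 on the log2 scale. CPH18, CPH19, CPH20, CPH21, CPH22 and CPH23 follow one another among the tested genes placed on the RefSeq assembly ASM3026992v2. They lie in 1 run of 7 such neighbours that were all higher in GMS. Genes not tested or not placed were skipped. Other cuticular genes fell: CPH33 went from 21.2 ± 0.234 to 2.43 ± 0.226 CPM, and CPR25 and CPT1, both among the 10 cuticular genes of highest level in WT, fell by 0.86 and 0.69 on the log2 scale. CP8, named for the cuticle as well, fell by 1.79. Of 75 tested cuticular protein genes, 27 rose, 22 fell and 26 did not pass, and the list as a whole was not called (camera adjusted p = 0.233), though it was among genes with at least 1 CPM in at least 3 libraries (camera adjusted p = 0.00516; adjusted p = 0.388 with an estimated correlation). The list of epidermis and cuticle genes fixed beforehand gave 15 rises and 16 falls among 54 genes, and 18 rises and 17 falls when adjusted over the list alone (camera adjusted p = 0.539). These are families of similar genes, and reads may have been divided between close copies.

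**Figure D2:**
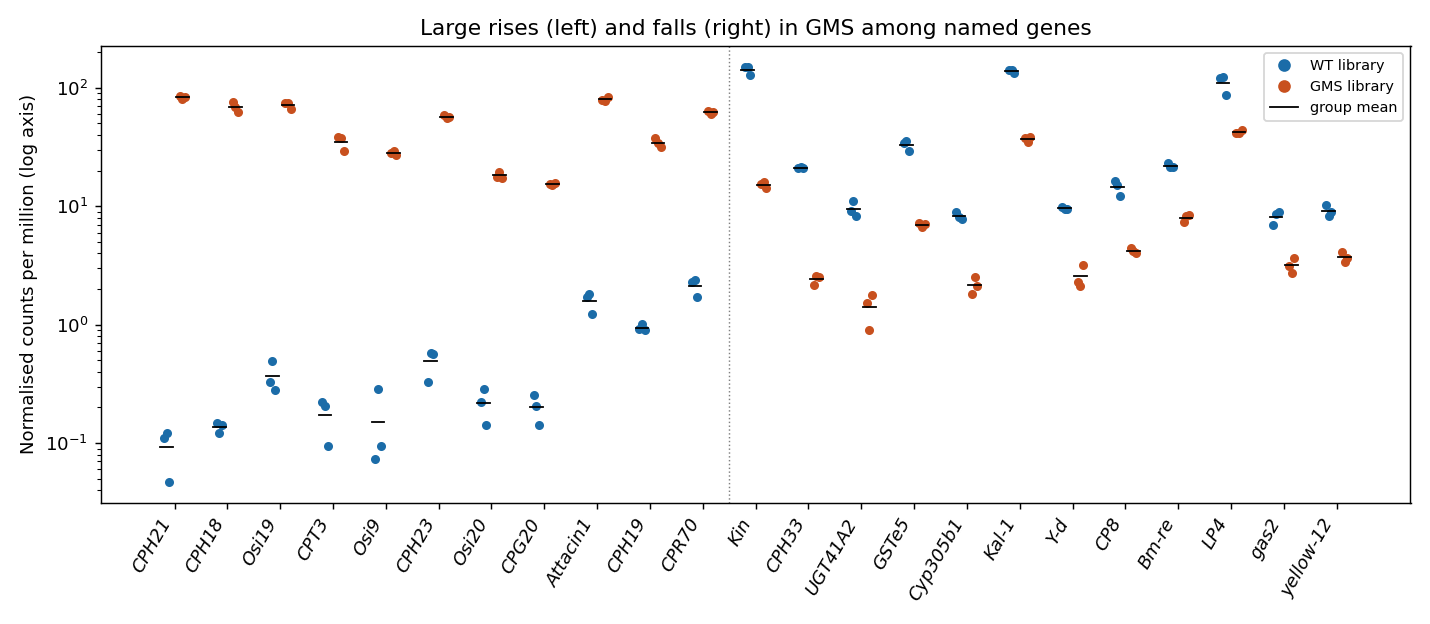
Normalised read counts as CPM on a log axis for 11 large rises and the 12 largest falls in GMS among genes with a name. Each point is 1 library, blue for WT and orange for GMS, and bars are means of 3 libraries. CPH21 lies at a mean of 0.0934 in WT and 83.4 in GMS, and Kin at 143 and 15.1, with no overlap between the groups for any gene drawn.

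Osiris genes, an insect-specific family of membrane proteins, rose as well. Osi19 increased from 0.368 ± 0.109 to 72.1 ± 4.93 CPM, Osi9 from 0.151 ± 0.117 to 28.3 ± 1.20 CPM and Osi20 from 0.216 ± 0.0726 to 18.3 ± 1.15 CPM (SD, n = 3). The log2 changes were 7.59, 7.50 and 6.35, with standard errors of 0.15, 0.25 and 0.18. Osi18 and Osi7, named after their values were seen, rose by 4.32 and 1.82. No list of this family was fixed, so it has no test as a group.

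Most of the antimicrobial and immune genes tested were higher in GMS. Attacin1, a peptide against Gram-negative bacteria, rose from 1.58 ± 0.313 to 79.8 ± 3.52 CPM (SD, n = 3; log2 change 5.64, standard error 0.13). Leb3, a lebocin, rose by 4.18, the gloverins glv3 and glv4-like by 4.73 and 4.63, and the lysozyme gene Lzm by 4.32. Of the 12 tested members of the list fixed beforehand, 11 rose and none fell, both over all genes and adjusted over the list alone, with a median log2 change of 1.47 (camera adjusted p = 3.71e-08). This call held with an estimated correlation over all 6 libraries, at an adjusted p of 0.0248, but not with any 1 library left out, where the adjusted p with an estimated correlation was 0.0566 to 0.216, the highest without WT replicate 3. Of the 25 genes of the longer list written from gene symbols, 19 rose and 0 fell, 19 and 1 adjusted over the list alone. With upper-quartile factors 18 rose and 1 fell. The median of this list was 1.08 (camera adjusted p = 8.93e-08, and camera adjusted p = 0.475 with an estimated correlation). Enb3, with no reads in WT and 71 in GMS, was at least 23.4-fold higher against a floor of 3 counts over the group.

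Markers of other tissues did not move together. Among 12 fat body and haemolymph genes 0 rose and 8 fell, with a median log2 change of -1.04 (camera adjusted p = 0.00148; adjusted p = 0.475 with an estimated correlation). LP4, a low molecular mass lipoprotein, went from 110 ± 19.5 to 42.3 ± 1.56 CPM, and LP3, Lp-c6 and Lp-c23 fell by 1.07, 1.12 and 1.19 on the log2 scale. Of 9 haemocyte genes, 4 rose and 3 fell: the phagocytosis receptor gene NimB rose by 1.02 and the prophenoloxidase gene PPO2 by 0.76, while the prophenoloxidase-activating enzyme gene PPAE fell by 0.71 and Scr-c by 1.26. Of 10 muscle genes 3 rose and 3 fell, of 5 gut genes 0 rose and 3 fell, and of 13 nervous tissue genes 1 rose and 2 fell. None of these last 4 lists was called (camera adjusted p from 0.323 to 0.976).

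**Figure D3:**
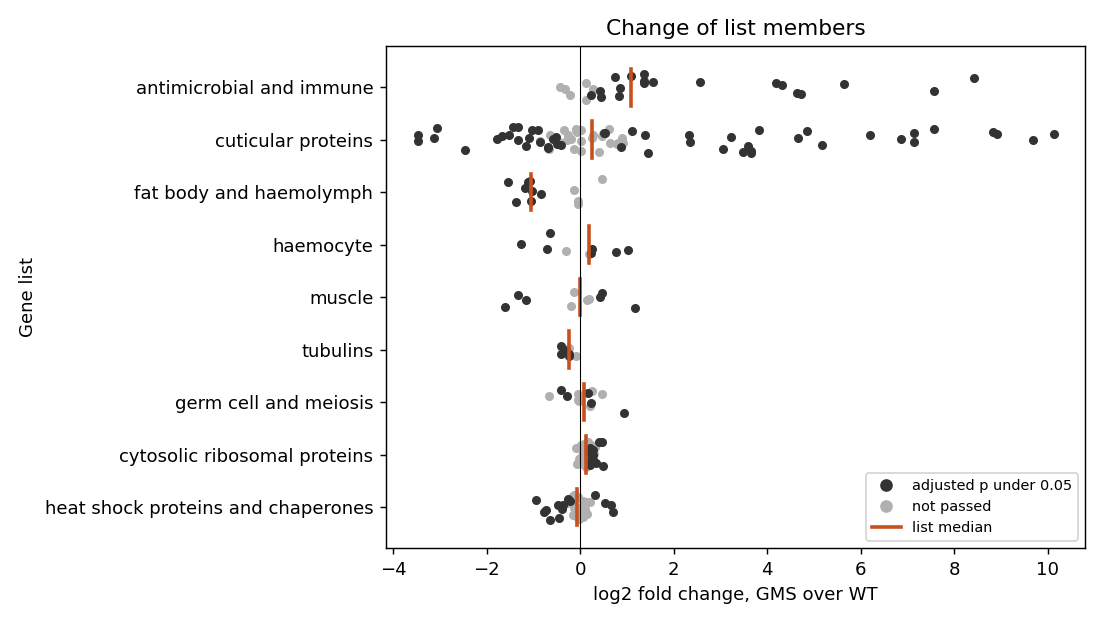
The log2 fold change of GMS over WT for each tested member of 9 gene lists. Each point is 1 gene, dark where its adjusted p was under 0.05, and the orange line is the list median. The antimicrobial list has a median of 1.08, the fat body and haemolymph list a median of -1.04, and cuticular proteins spread to both sides.

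Of 12 germ cell and meiosis genes 3 rose, 2 fell and 7 did not pass (camera adjusted p = 0.976). Dmc1, the meiotic recombinase, rose from 9.04 ± 0.726 to 17.2 ± 0.993 CPM, and the piRNA pathway gene Aubergine rose by 0.23 on the log2 scale. The 2 that fell were the testis-specific serine kinase gene TSSK, by 0.29, and Tub4, which is also in the tubulin list. Of 7 tubulin genes 0 rose and 5 fell, Tub4 by 0.40 and Tua2 by 0.34. Camera called the list with the preset correlation (adjusted p = 0.0405) but not with an estimated correlation (adjusted p = 0.656). It was also called by fry (adjusted p = 0.0323), which does not compare a list with other genes. The camera call was lost with DESeq2 size factors (camera adjusted p = 0.0595) and with upper-quartile factors (0.0882). It was also lost without each library but WT replicate 3 (0.0656 to 0.0880) and without the genes of largest change and the 10 most abundant genes (0.147). Without WT replicate 3 the camera adjusted p was 0.00548. The list median was -0.24, and -0.27 with DESeq2 size factors. Of 76 cytosolic ribosomal protein genes, 15 rose and 0 fell, 10 and 0 adjusted over the list alone, with a median of 0.12, and RpS12 rose by 0.47 and RpL41 by 0.49. That list was called as well (camera adjusted p = 0.00143; adjusted p = 0.675 with an estimated correlation), but not without WT replicate 3, where the adjusted p was 0.544. Of the 76 ribosomal genes, 10 rose with DESeq2 size factors, 4 with upper-quartile factors and 57 with library totals only.

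Heat shock genes included large transcripts that fell. Hsp90 went from 6418 ± 474 to 3864 ± 37.2 CPM (SD, n = 3), and Hsp23.7 and Hsp20.1 fell by 0.94 and 0.78 on the log2 scale. Of 37 heat shock and chaperone genes 4 rose and 10 fell, 4 and 11 adjusted over the list alone, and the list was not called (camera adjusted p = 0.152). Its median was -0.06 and turned to 0.04 with library totals only. Of 20 genes of serpins, which are serine protease inhibitors, 5 rose and 5 fell over all genes and over the list alone (camera adjusted p = 0.872), and of 6 apoptosis and autophagy genes 2 rose and 1 fell, with the same counts over the list alone (camera adjusted p = 0.212). The caspase gene Casp-4 rose by 1.49. Of the 17 genes of the symbol list 2 rose and 3 fell (camera adjusted p = 0.618), among them aif, which fell by 0.52, and ICE, with 92 reads in WT and 4 in GMS, a ratio of 23.2 (interval 8.77 to 87.1).

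Cyp18a1, a cytochrome P450 that breaks down ecdysteroids, went from 8.07 ± 0.666 to 86.0 ± 2.01 CPM (SD, n = 3; log2 change 3.41, standard error 0.08), and the juvenile hormone esterase gene jhe1 from 4.48 ± 0.488 to 15.6 ± 0.423 CPM. The nuclear receptor genes Hr3 and Ftz-f1, which act in the ecdysone response, rose by 0.48 and 0.61, though Ftz-f1 missed the threshold without GMS replicate 1 or GMS replicate 3 (edgeR adjusted p = 0.0523 and 0.0529). Of 6 ecdysone and juvenile hormone genes fixed beforehand 2 rose and 0 fell, 3 and 0 over the list alone (camera adjusted p = 0.180), and of 25 genes of the symbol list 6 rose and 4 fell (camera adjusted p = 0.719). The median of the symbol list was 0.04 and turned to -0.02 with upper-quartile factors.

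Among the other large falls was Kin, which went from 143 ± 12.6 to 15.1 ± 0.883 CPM (SD, n = 3; log2 change -3.24, standard error 0.09). The glycosyltransferase gene UGT41A2, the glutathione transferase gene GSTe5 and the cytochrome P450 gene Cyp305b1 fell by 2.73, 2.24 and 1.93 on the log2 scale. Kal-1 fell from 139 ± 4.61 to 36.8 ± 1.75 CPM. The pigmentation genes Y-d, Bm-re and yellow-12 fell by 1.90, 1.45 and 1.30, and gas2 fell by 1.35. Of 72 detoxification genes 13 rose and 18 fell (camera adjusted p = 0.323).

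The strains may carry different genes or alleles, so genes seen in 1 strain only were counted. A total of 28 genes had 0 reads in all 3 libraries of one strain and at least 10 in each library of the other, 15 in GMS only and 13 in WT only. LOC105841496, with 1257 reads in GMS and 0 in WT, was at least 415-fold higher in GMS. LOC101741602, with 1057 reads in WT and 0 in GMS, was at least 356-fold lower in GMS. The bounds use a floor of 3 counts over the group and cover counting error only. LOC105841584 and LOC110385144, both long noncoding RNAs, were at least 223-fold and 212-fold lower, and GeneID101735534 and LOC101735346 at least 234-fold and 179-fold higher. LOC101743424 and GeneID101743359 each had 1 read in WT, with ratios of 2640 (interval 474 to 104000) and 2320 (interval 416 to 91700). LOC101745554 and LOC110386596 were lower in GMS, with ratios of 194 (interval 75.6 to 715) and 134 (interval 64.7 to 334).

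Changed genes lay next to each other more often than random orders gave. A male sterile line can carry a stretch of donor genome around its mutation, which is why the positions were compared. Of 10527 tested genes placed on 28 chromosomes of the RefSeq assembly ASM3026992v2, 1032 differed by at least 2-fold. They formed 235 neighbouring pairs, against a mean of 109 and a highest value of 143 in 10000 random orders within chromosomes (one-sided permutation p = 0.0001, the smallest these orders can give). The share of changed genes departed from the rest on 5 chromosomes, above on 3 and below on 2 (2-sided Fisher's exact test, adjusted over chromosomes). That test takes genes as independent, so its p-values may be too small for neighbours that change together. With cuticular, Osiris and antimicrobial genes counted as unchanged, chromosome 26 was no longer above (Fisher adjusted p = 0.114), while chromosomes 3 and 28 were. Among the longest runs of neighbours changed in the same direction were 7 genes with the CPH cluster and 6 genes with CecB1 and Enb3, both higher in GMS, and 5 genes with LP3, LP4 and Lp-c6, lower in GMS. The 19 placed genes seen in 1 strain only formed 0 neighbouring pairs, against a mean of 0.09 in random orders. With so few genes most random orders would give 0 pairs too, so this count does not exclude some clustering. Their share was above the rest on chromosome 7, with 4 of 286 genes (Fisher adjusted p = 0.0419).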

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

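The symbol lists were written after the identifiers had been seen, and were run through the alternatives planned for the other lists. Some settings were chosen after seeing the data. These were the limma-voom fit with sample quality weights, and an estimated correlation without each library or with a filter of 1 CPM. The cluster settings with gene families counted as unchanged, at a distance and without each chromosome were also among them. Those at a distance and without each chromosome were set before their own results. Leaving out 1 library at a time gave 2999 to 7104 changed genes, 1161 to 1585 genes of at least 2-fold, 1 to 2 gene lists called and 2 to 5 symbol lists called. The upper end, and the loss of the ribosomal list, came from leaving out WT replicate 3. Quality weights gave 7311 changed genes, with a weight of 0.193 for that library against 0.964 to 2.38 for the others. RPKM values gave 359 genes of at least 2-fold with a pseudocount of 1 and 334 with a mean value of at least 1, and 1033 with a pseudocount of 0.1, so the pseudocount lowered the count. An estimated correlation left 1 of 2 gene lists and 0 symbol lists called (with 3 at the preset correlation and 16 by fry), and fry called 5 gene lists. With an estimated correlation 0 gene lists and 0 symbol lists were called with 1 library left out, whichever it was, and 1 and 0 among genes with at least 1 CPM in at least 3 libraries. A minimum of 50 counts left 10 genes listed in one strain only, since fewer genes could pass. For the 19 placed genes listed in one strain only, clustering gave 0 pairs and 1 uneven chromosome. With cuticular, Osiris and antimicrobial genes counted as unchanged among the same 10527 genes, 8 chromosomes were uneven, 4 above and 4 below. This recount in itself lowers the share on chromosomes that hold such genes, as on chromosome 11, from 44 to 36 of 620 genes. Other causes were not tested. The replicate numbers did not pair the samples (correlations 0.05, -0.17 and -0.17), and the replicate block gave 3151 changed genes, 1158 of at least 2-fold, 2 gene lists and 3 symbol lists. The 145 genes taken by the naming rule or named besides gave 2580 values. Of these, 2411 stayed on their side of the threshold, 144 lost the threshold and 25 gained it, in 29 genes. Direction reversed in 0 values where the gene passed in the main fit or in the alternative. Changes of direction where it passed in neither were not counted. On simulated counts of these depths 55.2% of 67 genes at 1.5-fold were recovered.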

Other observations

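The tests on WT replicate 3's label and mixing, on tissue markers and on cuticular genes were chosen only after the result was seen, and those of neighbour distance and single chromosomes after the excess of neighbouring pairs was seen but before their own results; what would exclude genome blocks, haemocytes and epidermis was made stricter after their results. Among genes the report does not describe, SPARC, a glycoprotein of basement membranes, rose from 214 ± 5.15 to 401 ± 10.2 CPM (SD, n = 3), a log2 change of 0.91. The chemosensory protein genes CSP9 and CSP1 rose by 2.32 and 1.52, and Snmp1 fell by 1.52. The DNA damage genes FANCI and p53 rose by 0.63 and 0.92, and the replication and cell cycle genes Cyce, Cap-d3 and Cdt1 by 0.77, 0.77 and 0.37, though Cdt1 missed the threshold without GMS replicate 2 (edgeR adjusted p = 0.0565).

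WT replicate 3 resembled GMS over one set of genes and WT over others. Of the 195 genes over 2-fold higher in it than in both other WT libraries, 187 lay within 2-fold of the GMS mean. The telomerase gene Tert stood at 5.40, 3.77 and 36.8 CPM in WT replicates 1, 2 and 3 and at 59.0, 58.8 and 55.6 CPM in GMS, and FANCD2 at 66.3, 51.3 and 188 CPM in WT and 206, 223 and 210 CPM in GMS, and neither passed the main test. GeneID110386648 stood at 0.110, 0.205 and 496 CPM in WT and 301, 433 and 286 CPM in GMS.

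After WT replicates 1 and 2 were thinned to the same depth, 188 genes were over 2-fold higher in WT replicate 3, against 195 before. These genes had a mean of at least 5 CPM, far above the floor, so thinning could hardly remove a 2-fold gap. It was therefore no strong test of the depth of WT replicate 3. GMS RNA mixed into the library would move all genes by 1 share: over 155 of the 195 genes that were also higher in GMS the median was 108% of the way to GMS, but over 51 genes under 1 CPM in the other WT libraries and at 5 CPM or more in GMS it was 0.01%, with 5 of the 51 over 50%. Among 33 genes seen in 1 strain only, judged without this library, it went with WT in 32, which argues against a GMS library under a WT label. Blocks of genome that differ between WT animals may be the source, but the 161 placed genes formed 6 neighbouring pairs against a mean of 3.26 and a highest of 12 in random orders (one-sided permutation p = 0.105), so this stays open, as does a difference in stage, which was not tested.

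The rise of antimicrobial genes, of the Osiris genes named and of 27 of 75 cuticular protein genes, whose list was not called, might come from other tissue carried with the testis. More fat body of the same make-up would raise its markers, but of 12 genes 0 rose, 8 fell and 4 did not pass. LP3, LP4 and Lp-c6 lie in 1 run of 5 neighbours lower in GMS, so their falls are not separate readings of tissue amount. The counts argue against more fat body only if the markers follow tissue amount and do not differ between the strains themselves. The median log2 change of the 12 genes was -1.04 (camera adjusted p = 0.475 with an estimated correlation). The storage protein genes Sp1 and Sp2, at 15.2 and 1.46 CPM in WT, stood at 7.44 and 0.492 CPM in GMS. They were chosen after their values were seen and add no support. More haemocytes stay open, since of their 9 markers 4 rose, 3 fell and 2 did not pass. More epidermis stays open too: of the 10 cuticular genes of highest WT level 0 rose and 8 fell, but their WT levels of 12.1 to 1084 CPM could hide an added share, as the 27 cuticular genes that rose gained a median of 8.40 CPM. Cells of another kind, such as trachea, an immune response, and a difference between the strains in the timing of the moult stay open as well, and were not tested.

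The excess of neighbouring changed pairs might come from reads shared by overlapping or close gene models. Counting only neighbours at least 5 kb apart left 148 pairs, against a highest of 70 in 10000 random orders, which argues against that. A single block of donor genome would place the excess on 1 chromosome. Leaving out each of the 28 chromosomes in turn left 218 to 234 pairs, against a highest of 148 in 1000 random orders each. This argues against 1 block as the source of the whole excess. It does not exclude a block that adds to pairs from other sources. Tandem gene families that are expressed together stay open. With cuticular, Osiris and antimicrobial genes counted as unchanged, 204 pairs remained, against a mean of 98.8, but other families could not be named from symbols.

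Other groupings of the 6 libraries make 10 splits in all, too few for a share under 0.05. The real split gave 4357 changed genes and 1238 of at least 2-fold, and the highest other split gave 0 of each. It was as large in 1 of 10 splits for both. Every other split puts both strains in each group, so the strain difference adds to the spread within groups. The 0 calls therefore do not show what chance would give. For the list tests, 7 of 10 splits gave at least the 2 gene lists called in the real one, with a highest other value of 2, and 2 of 10 gave at least the 3 symbol lists called, with a highest other value of 3. Splits that mix the strains thus reached the same counts of lists. They still hold unequal shares of the strains, so they do not measure how many lists chance would call.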
